A study of Mus musculus with 2 samples.

How the data were processed

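Small-RNA libraries (size range under 30 bases, per the labels) were made from total RNA of facial prominence tissue of B6NCrl mouse embryos at day 11.5. There were 2 libraries, 1 for each biological replicate. Both pools carry the same donor entry in the labels, which number them as separate biological replicates; no sequencing date or batch was given in the sources used here.

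The authors deposited raw counts per microRNA gene, per the file that accompanies each table for mm10 with the GENCODE M4 annotation. The aligner, its version and the counting program were not given in the sources used here. Each table has 3 count columns (irrespective of strand, sense and opposite strand) and 4 further lines for reads that name no gene, a layout like that of STAR's gene counts. The column irrespective of strand equalled the sum of both strands at all 1973 loci. The sense column held 96.9% ± 0.14 (SD, n = 2) of the stranded counts and was used. The lines that name no gene were left out of library sizes. In replicate 1 they were 30.9% unmapped, 22.7% placed at several positions and 5.51% assigned to no locus on the sense strand, and 40.8% of 4755968 reads were assigned on that strand. In replicate 2 they were 38.6%, 20.5% and 6.75%, with 34.2% of 6781929 reads assigned. Because the class placed at several positions is kept apart, counts at loci with near-identical copies are incomplete. No molecular identifiers are named in the labels, so counting intervals and the limit from a count of 0 (3 counts) cover counting error only.

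Symbols, positions (1-based) and host genes came from GENCODE M21, which uses the same GRCm38 (mm10) assembly. Of 1973 identifiers, 1894 matched when versions were ignored and 1815 with the version; the 79 unmatched held 4 counts in all. Of 198 loci on the fixed lists, 180 were matched; the others were not analysed here. Hairpin sequences of the matched loci were compared on both strands, and a locus was called shared when at least 20 bases in a row occurred in a hairpin at another position.

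CPM was computed per total of sense counts. Correlations and list levels used log2(CPM + 1). Detection meant at least 10 counts in both libraries. Loci were compared between pools where the mean count was at least 100, by the ratio of CPM; 95% intervals came from the exact (Clopper-Pearson) binomial interval of the counts. Differences between the erythroid loci were given a normal-approximation 95% interval with the edgeR coefficient of variation added to counting error. The median level of each list was placed among 10000 random lists of the same size from the loci with a count in either library. The median log2 ratio between pools (0.5 counts added, mean count of at least 10) was placed among 10000 random lists matched on deciles of level. Percentiles above 97.5 or below 2.5 were called, for lists with at least 3 members. Clusters were runs of loci on 1 strand at most 10 kb apart. A difference between 2 loci was called larger than the replicate difference when its size in each library exceeded the log2 ratio between pools of both loci. With 1 group, no test between conditions exists, and edgeR was used only for the dispersion of an intercept-only model. Tests over loci used 100000 permutations. Library factors came from edgeR 4.0.16 (TMM) and DESeq2 1.42.0 under R 4.3.3; other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

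The lists (mesenchyme, epithelium, neural, striated muscle, erythroid, leukocyte, endothelium, liver and gut, pluripotency, Mir17 clusters, let-7, Hox clusters, Dlk1-Dio3 imprinted, other imprinted, Mir322 and Mir503 cluster, sensory, endocrine, ciliated epithelium), the tests and the rule for naming loci were fixed before the data were examined. The rule names the 20 most abundant loci, the 4 most abundant of each list with members used in pairwise comparisons, the 5 highest and 5 lowest ratios between pools among loci with a mean count of at least 100, and up to 10 loci with copies. Choices made after values were seen were the pairs of loci compared within clusters and lists, the naming of Mir200b, Mir133b, Mir145a, Mir106a, Mir199a-2 and Mir299b, the dispersion as a reported value, the families of the closing part, the minimum of 100 opposite-strand counts, the crediting of opposite-strand counts to an overlapping gene there, the permutation over neighbouring loci only and the classing of loci by shared hairpin. That classing also takes in distinguishable paralogs such as Mir23b and predicted gene families, 929 of 1894 loci in all.

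The steps were tested on simulated libraries with the means and library sizes of the 708 loci and the dispersion above. With 200 loci changed by 4-fold, 99.8% of those with a mean count of at least 100 passed the 2-fold limit and 0.56% of unchanged ones did. With a 2-fold change 51.0% passed, since a change equal to the limit falls on either side of it. These changed loci were limited to levels under 1000 CPM, a limit set after a first simulation. With abundant loci among the changed ones, 1.14% of unchanged loci passed at 2-fold, 5.20% at 4-fold and 45.0% at 8-fold, because changes in abundant loci shift the CPM of all others. The CPM ratios are therefore unreliable where abundant loci change by 4-fold or more. Among 400 simulated lists of 8 loci, 3.75% of unchanged lists and 100% of lists whose ratios were shifted by 2-fold were called. These lists held independent loci, and the shift was larger than the median of every list called below except muscle. The simulation therefore does not show how smaller shifts or lists of neighbours are called. The number of list simulations was raised after a first, smaller set had called random lists by level more often. Random lists were called by level in 4.25% of 400 runs. Alternatives were counts irrespective of strand, other count minimums and pseudocounts, TMM and DESeq2 scaling, leaving out the most abundant locus, thinning the deeper library, leaving out numbered copies and leaving out each replicate.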

Results

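MicroRNA levels were measured by small-RNA sequencing in the facial prominences of mouse embryos at embryonic day 11.5. These prominences are the swellings of mesenchyme, much of it derived from neural crest, and covering epithelium that grow and fuse to form the face. There was 1 group with 2 biological replicates, each a pool of tissue from many B6NCrl embryos of both sexes: 109 embryos in replicate 1 and 88 in replicate 2. The sense strand of annotated microRNA loci received 1941745 counts in replicate 1 and 2319881 in replicate 2, so 1 count stood for 0.515 and 0.431 CPM (counts scaled to a library total of 1e+06). The labels name no treatment, genotype or second tissue. The comparisons are therefore between loci within the same libraries, between groups of loci fixed before the data were examined, and between the 2 pools. Values are given as the mean ± SD over n = 2, and the 2 libraries allow no two-sided exact test to go below p = 0.5. All intervals below cover counting error only, except those of the differences between erythroid loci, which also include the spread between pools.

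Which microRNAs make up the facial prominence profile was addressed first. The most abundant locus was Mir335, which lies in an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396, plus strand), at 87317 ± 5140 CPM. Mir17, the first member of the growth-associated Mir17 to Mir92-1 cluster in an exon of Mir17hg (chromosome 14, 115043671 to 115043754, plus strand), followed at 67180 ± 577 CPM. Mir335 exceeded Mir17 by a log2 ratio of 0.38 ± 0.07, which was larger than the difference between the replicates for either locus. Mir99a stood at 48296 ± 1192 CPM, the endothelial Mir126a in Egfl7 at 39731 ± 981 CPM, and Mir130a at 36133 ± 2136 CPM. Mir99b, Mir322 and the mesenchymal Mir214, which lies in Dnm3os, had 35253 ± 3050, 32601 ± 3034 and 29999 ± 2093 CPM. Mir23b and Mir30e closed the first 10 places at 27209 ± 268 and 25858 ± 1213 CPM. Places 11 to 20 were held by Mir20a, Mir26b, Mirlet7g, Mir93, Mir183, Mir182, Mir143, Mir100, Mir652 and Mirlet7i, from 23448 ± 1001 CPM for Mir20a to 13154 ± 530 CPM for Mirlet7i.

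The profile was concentrated in few loci. The 10 most abundant took 43.0% ± 0.0243 of all sense counts at the loci, the first 20 took 58.6% ± 0.341, and the first 50 took 82.3% ± 0.0278. Reads placed at several positions are outside these counts, so loci with near-identical copies may rank too low. Of the 1973 loci in the count tables, 351 reached at least 10 counts in both libraries, 708 had at least 1 count in either, and 1265 had 0 in both. A count of 0 in a library allows a level of up to 1.55 CPM in replicate 1 and 1.29 CPM in replicate 2. Lowering the minimum to 1 count in both libraries raised the number of detected loci to 563.

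Many loci listed as markers of the tissues that make up the prominences were abundant. How specific each listed locus is to its tissue was not tested. Of the 15 measured loci of the mesenchyme list, all reached at least 10 counts in both libraries. Together they took 9.64% ± 0.196 of the counts, led by Mir214, Mir23b, the smooth-muscle and mesenchyme locus Mir143 at 13677 ± 719 CPM, and the cartilage-associated Mir140 in Wwp2 at 8587 ± 460 CPM. All 7 epithelial loci were detected and took 3.13% ± 0.251. Mir429 and Mir205 stood at 8239 ± 458 and 8049 ± 165 CPM, the skin-associated Mir203 at 6028 ± 381 CPM and Mir200c at 4793 ± 747 CPM. The mesenchymal share was above the epithelial share in both libraries (9.50% against 3.31% in replicate 1, and 9.78% against 2.95% in replicate 2), as a sum over 15 against 7 loci. The median level per locus was higher for epithelium, at 4793 CPM, than for mesenchyme, at 1361 CPM. Shares of counts are not shares of cells. The endothelial list was represented by Mir126a alone, which took 3.97% ± 0.0981.

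Loci of the proliferation-associated Mir17 clusters took 14.7% ± 0.195 of the counts, the highest share of any list. Among them were Mir17, Mir20a, Mir93 at 15642 ± 181 CPM and Mir18 at 12823 ± 726 CPM. Mir17 exceeded Mir106a, its counterpart in the X-linked cluster, by a log2 ratio of 4.76 ± 0.01. Imprinted loci were also high. In the list of the maternally expressed Dlk1-Dio3 region on chromosome 12, 43 of 48 measured loci reached 10 counts in both libraries and took 7.33% ± 0.268, led by Mir411 at 10487 ± 853 CPM, Mir487b at 8172 ± 359 CPM, Mir431 at 7153 ± 948 CPM and Mir379 at 5185 ± 227 CPM. Counts opposite loci that overlap further members, such as Mir409, are outside this share. With them credited to those members it was 8.67% ± 0.447, of a total that also includes the opposite-strand counts credited to other genes. The other imprinted loci took 10.9% ± 0.391, mainly through Mir335, with Mir298 at 9105 ± 485 CPM, Mir296 at 8557 ± 716 CPM and the Igf2-hosted Mir483 at 3278 ± 321 CPM. The Mir322 and Mir503 cluster on the X chromosome took 3.83% ± 0.170. After Mir322, its most abundant members were Mir351 at 3206 ± 1247 CPM, Mir503 at 1203 ± 96.3 CPM and Mir542 at 936 ± 17.6 CPM. The sensory list took 3.47% ± 0.0393, led by the Mir183, Mir182 and Mir96 cluster of sensory cells and neurons.

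Median levels of the lists were set against the 708 loci with a count in either library. The median log2(CPM + 1) of 7 of 17 lists lay above the upper limit set for random lists of the same size. For lists of unrelated loci 0.85 would pass either limit by chance, and many members here are neighbours. The lists above the limit were the Mir17 clusters (percentile 99.99), the Dlk1-Dio3 list (100), mesenchyme (99.98), the other imprinted loci (99.96), epithelium (99.94), the sensory list (99.78) and the Mir322 and Mir503 cluster (98.5). The remaining 10 lists passed neither limit but also lay high, the lowest being liver and gut at percentile 70.2. Of the 708 background loci 363 had a mean count of at least 10, so the background itself favours high percentiles. The 0.85 is therefore a weak yardstick for these levels. The percentiles describe these libraries, since loci are not replicates. When only loci with a mean count of at least 10 were used, 6 lists passed: the Mir322 and Mir503 cluster was at percentile 87.0, and the neural and let-7 lists, not called in either case, were at 17.5 and 40.0.

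**Figure D1:**
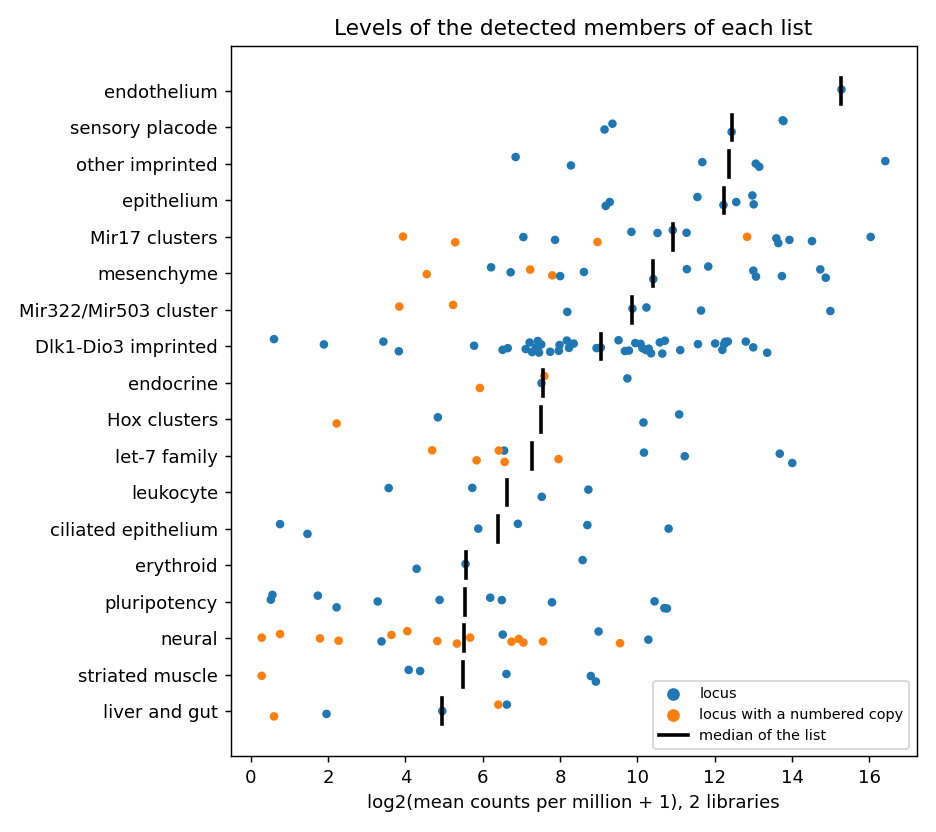
Horizontal axis, log2 of mean CPM plus 1 over the 2 libraries; each line is a fixed list, each point a detected locus, orange for symbols with a numbered copy, and the bar is the list's median. The medians of the Mir17 clusters, mesenchyme, epithelium, sensory and imprinted lists lie to the right of those for neural, muscle, blood and liver lists.

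Lists of other cell types took small shares of the counts, and none of them passed the lower limit of the level percentiles. Shares are incomplete where loci have near-identical copies. Numbered copies made up 15 of the 19 measured neural loci and 3 of the 8 measured muscle loci. The neural list took 0.330% ± 0.0394, with Mir137 at 1384 CPM in replicate 1 and 1109 CPM in replicate 2, and Mir219a-2 at 750 ± 139 CPM. The pluripotency list took 0.522% ± 0.0425, led by the Mir302 cluster, with Mir302a at 1739 ± 121 CPM, Mir302d at 1660 ± 202 CPM and Mir302b at 1392 ± 117 CPM. Mir302a exceeded Mir294, of the embryonic stem cell cluster on another chromosome, by a log2 ratio of 4.29 ± 0.19. Loci of the Hox clusters took 0.334% ± 0.0947, with Mir10a at 2165 ± 649 CPM and Mir10b at 1142 ± 298 CPM, while Mir196b had 27.6 ± 2.5 CPM. The endocrine list took 0.129% ± 0.00536, led by Mir375 at 855 ± 30.2 CPM. The ciliated-epithelium list took 0.239% ± 0.0491, led by Mir34c at 1792 ± 318 CPM. The leukocyte list took 0.0670% ± 0.00739, led by Mir223 at 424 ± 59.3 CPM. With the counts opposite Mir142b credited to its overlapping member Mir142 (919 CPM), a step chosen after the values were seen, the leukocyte share was 0.154% ± 0.00498. The liver and gut list took 0.0215% ± 0.00149, led by Mir192 at 96.3 CPM in replicate 1 and 98.7 CPM in replicate 2. The muscle and erythroid lists took 0.106% ± 0.0613 and 0.0447% ± 0.0236, and are the 2 lists with the largest ratio of shares between the pools (2.38-fold and 2.19-fold).

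Levels of loci within a cluster or family were compared in pairs. Mir143 exceeded its neighbour Mir145a by a log2 ratio of 5.76 ± 0.23. Mir214 exceeded Mir199a-2, its neighbour on chromosome 1, by 7.08 ± 0.05, but Mir199a-2 has copies that share its sequence, so its level is uncertain. In the let-7 family, which took 3.38% ± 0.311 (3.91% ± 0.339 with such opposite-strand counts, mainly at Mirlet7e), Mirlet7g stood at 16461 ± 2210 CPM and Mirlet7i at 13154 ± 530 CPM, and Mirlet7g exceeded Mirlet7d by 2.78 ± 0.06. Within clusters, the most abundant locus was set against each other member with a mean count of at least 10, and other pairs of neighbours were not compared. Of these 112 pairs, 108 had a difference that exceeded the replicate difference of both loci in each library. The exceptions were Mir183 and Mir182 (0.03 ± 0.25), Mir298 and Mir296 (0.09 ± 0.04), Mir302a and Mir302d (0.07 ± 0.08), and Mir192 and Mir194-2 (0.23 ± 0.17). Mir302a and Mir194-2 share at least 20 bases with another hairpin, so their levels may be incomplete. Levels of loci in one library also carry differences in how well each sequence is ligated, amplified and placed at 1 position.

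Loci that share sequence with a copy elsewhere can lose reads to the class placed at several positions, which held 32.9% of the mapped reads in replicate 1 and 33.3% in replicate 2. Mirlet7a-1 and Mirlet7a-2 had 56.3 ± 10.7 and 93.7 ± 0.8 CPM, and the muscle loci Mir133a-1 and Mir133a-2 had 0 counts in both libraries, as did the neuronal Mir124a-3. Levels of such loci are uncertain. Opposite to the direction anticipated in the planned test, over all 1973 loci symbols with a numbered copy were less often at 0 than other symbols (60 of 121, or 49.6%, against 1205 of 1852, or 65.1%), a difference of -15.5 percentage points (two-sided permutation test over loci, p = 0.00073). The direction turned when loci were classed by hairpin sequence instead, a setting chosen after seeing the data. Loci sharing at least 20 bases with another hairpin were at 0 in 84.8% of cases against 41.5% for the rest, a difference of 43.4 points (permutation p = 1e-05, the smallest the test can give). The sharing class also takes in distinguishable paralogs and predicted gene families. The difference therefore does not show that sharing removes reads.

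The 2 pools were then compared, to ask how far the profile repeats between pools that the labels number as separate biological replicates. Across the 708 loci with a count in either library, log2(CPM + 1) had Pearson's r = 0.990 and Spearman's rho = 0.928; these are correlations across loci, which are not independent replicates. Among 257 loci with a mean count of at least 100, the median absolute log2 ratio was 0.14, and 238 loci (92.6%) lay within 0.5. The common biological coefficient of variation estimated by edgeR was 16.9%. The counts differed by far more than sampling noise (chi-square of 14731 with 362 degrees of freedom), so the libraries were not 1 library deposited under both names.

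**Figure D2:**
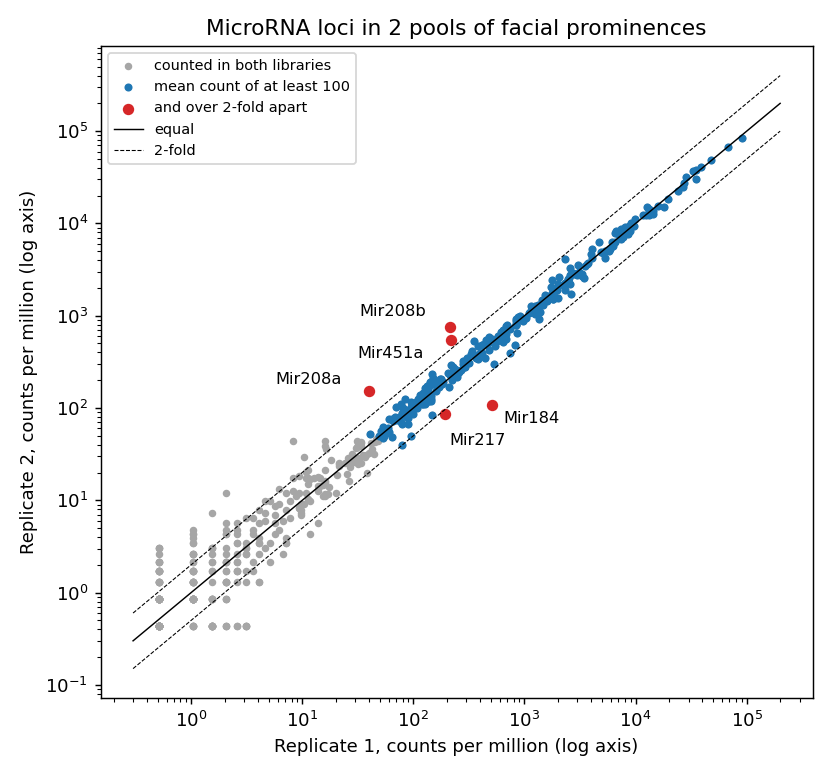
CPM of each locus in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, for loci counted in both libraries; the solid line marks equality and dashed lines a 2-fold difference. Of the 257 loci with a mean count of at least 100 (blue and red), the 5 in red lie outside the 2-fold lines.

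In all, 5 loci with a mean count of at least 100 differed by over 2-fold between the pools. Both Mir208a and Mir208b, in introns of the cardiac myosin genes Myh6 and Myh7 on chromosome 14, were higher in replicate 2. Mir208b (54975700 to 54975776, minus strand) had 212 CPM in replicate 1 and 758 CPM in replicate 2 (3.57-fold; 95% interval of the log2 ratio 1.68 to 2.00) and Mir208a (54949060 to 54949142, minus strand) had 40.2 and 153 CPM (3.82-fold; 1.58 to 2.31). The erythroid Mir451a (chromosome 11, 78073170 to 78073241) was also higher in replicate 2, at 547 against 218 CPM (2.51-fold; 1.17 to 1.49). Mir184, a locus known from lens and cornea (chromosome 9, 89802260 to 89802328), was higher in replicate 1, at 512 against 107 CPM (4.77-fold; log2 ratio -2.46 to -2.05). Mir217 (chromosome 11, 28763728 to 28763835) was higher in replicate 1 as well, at 194 against 85.8 CPM (2.26-fold; log2 ratio -1.43 to -0.93). The next in rank were Mir351 (log2 ratio 0.81) and Mir3102 (0.65) on the side of replicate 2, and Mir216b (-0.98), Mir1298 in Htr2c (-0.94) and Mir211 in Trpm1 (-0.90) on the side of replicate 1. The number past 2-fold depended on the count minimum: 13 loci with a mean count of at least 20, of which 10 were higher and 3 lower in replicate 2, and 3 loci with at least 500, of which 2 were higher and 1 lower.

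By list, the muscle loci were higher in replicate 2. Of 5 muscle loci with a mean count of at least 10, 4 were higher there and 3 by over 2-fold, with a median log2 ratio of 1.48 (percentile 100 among random lists matched on level). The third was Mir499 in Myh7b, with 20 and 68 counts. Mir206, a skeletal muscle locus, had a log2 ratio of 0.62, and its neighbour Mir133b had 0.00 (-0.73 to 0.74). The erythroid list passed neither limit (median 0.40, percentile 91.6). Its member Mir144, which lies beside Mir451a, had a log2 ratio of -0.02 (-0.44 to 0.40). In the liver and gut list Mir122, the main hepatocyte microRNA, had 31 and 102 counts, while the list's median was 0.03. The Dlk1-Dio3 list was shifted by a median of 0.10 toward replicate 2 (29 of 43 loci higher there, percentile 98.6). Its 1 locus past 2-fold, Mir299b, had 12 and 31 counts and is named after its values were seen.

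There were 5 lists that were lower in replicate 2. Among the Hox-cluster loci all 3 with a mean count of at least 10 were lower, with Mir10a at a log2 ratio of -0.62 and Mir10b at -0.54 (list median -0.54, percentile 0.38). All 7 epithelial loci were lower, with a median of -0.28 (percentile 0), from -0.04 for Mir205 to -0.32 for Mir200c and -0.40 for Mir200b. In the ciliated-epithelium list 3 of 4 loci were lower, including Mir449a at -0.84 (median -0.28, percentile 1.73). In the sensory list 4 of 5 were lower, with Mir204, hosted by Trpm3, at -0.77 and Mir211 at -0.90 (median -0.16, percentile 1.89), although the list's summed share was higher in replicate 2 (3.44% against 3.50%), where Mir182 had a log2 ratio of 0.27. In the let-7 list 9 of 10 were lower (median -0.14, percentile 2.20); with a minimum mean count of 50 its percentile was 2.74, past the limit no longer, and with opposite-strand counts credited it was 2.77. Together, 7 of 17 lists passed a limit. The 0.85 given by chance holds for lists of unrelated loci and understates chance for lists of clustered loci, since neighbours had similar ratios. Each of these values compares 2 libraries of 1 group, with no condition differing between them by the labels.

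**Figure D3:**
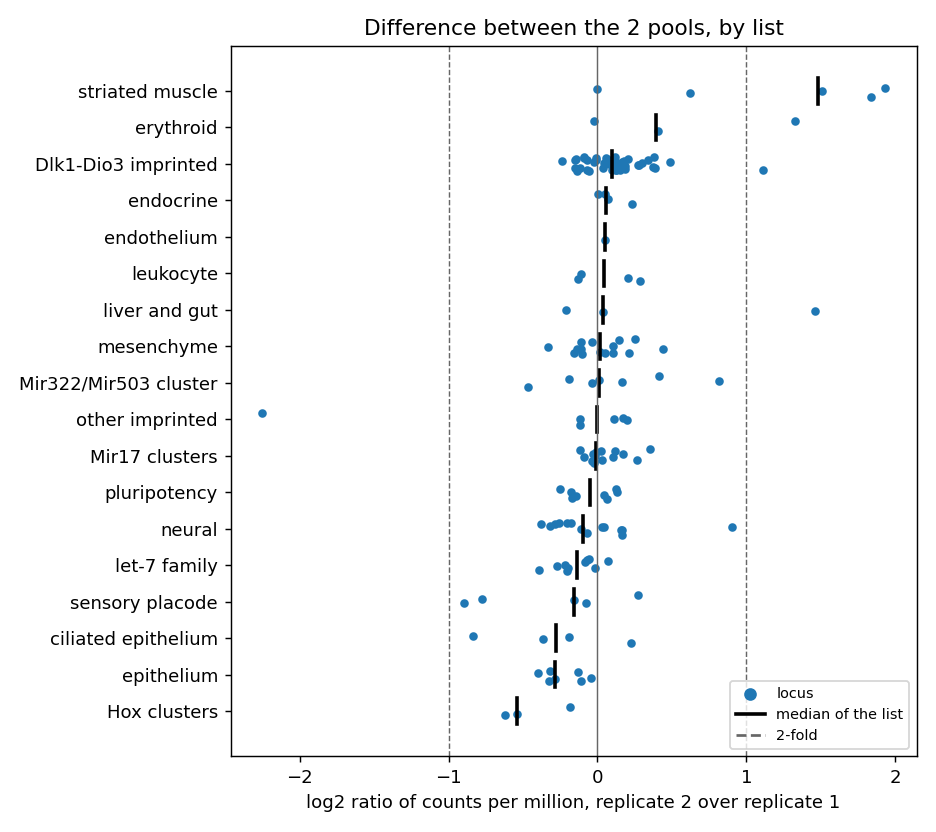
Horizontal axis, log2 ratio of CPM in replicate 2 over replicate 1; each line is a fixed list, each point a locus with a mean count of at least 10, the bar is the list's median and dashed lines mark 2-fold. The muscle list has a median of 1.48, and the Hox-cluster list the lowest, -0.54.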

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

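The tests on the opposite strand and on shared hairpins were chosen after the values were seen, while the comparison of numbered copies over all loci was planned.

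Counts on the opposite strand, which the comparisons above use only where credited to an overlapping gene, were far over the limit of 3 counts at 9 loci. Scaled to the sense total as CPM, they were 7794 at Gm24321, 6602 at Gm25927, 4760 at Gm25301, 4530 at Gm25252, 2905 at Gm24083, 2456 at Mir299b, 1454 at Gm25750, 919 at Mir142b and 804 at Mir497b (means of 2 libraries). A candidate source is a microRNA gene on the other strand: loci that overlap such a gene in GENCODE M21 held 99.9% of the opposite-strand counts, and all 9 do, their partners being Mir409, Mirlet7e, Mir378a, Mir376a, Mir191, Mir299a, Mir380, Mir142 and Mir497 in the order given. Incomplete strand marking is argued against, since loci with no such partner had 0.00472% of their counts on the opposite strand, against 3.15% over all loci. Where these counts belong to the partners, the leukocyte, let-7 and Dlk1-Dio3 shares are understated. Crediting them also raises the library total, on which all credited shares are based. Some other shares fall under it even with 1 member added: mesenchyme from 9.64% to 9.34%, endothelium from 3.97% to 3.85% and neural from 0.330% to 0.320%. The design names no biological difference that bears on this, so none was tested.

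Reads placed at several positions were 33.1% of the mapped reads (mean of 2 libraries), a class outside every comparison above. Numbered-copy loci on the fixed lists had a median log2(CPM + 1) of 5.26 against 9.17 for the other members, and reads shared between paralogs may account for this. All 38 of them share at least 20 bases with another hairpin, so a lower median of the 51 sharing members restates the pattern. The 13 sharing members that are no numbered copies had a median of 10.41 against 9.15 for the 129 that share none. This was a difference of 1.26 in the other direction (two-sided permutation test over loci, p = 0.368). It cannot decide the question, since these 13 include distinguishable paralogs such as Mir23b, whose reads can be placed at 1 position. The planned comparison over all loci, with numbered copies less often at 0 by -15.5 percentage points, cannot decide it either. Its other group held 1852 symbols, of which 1205 had 0 counts in both libraries. The explanation therefore stays open. Lower expression of the numbered-copy loci stays open too, since reads placed at several positions are not assigned to loci here.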

How the results depend on the processing

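The shared-hairpin classing and the crediting of opposite-strand counts were chosen after the values were seen. Of 823 recomputed values, 799 kept their side of the limit or stayed within the tolerance used for their measure. Some of these could not change. TMM and DESeq2 factors shift every log2 ratio by 1 constant, so list percentiles of the difference between pools stay the same under them. A kept value can still have moved far, since lists called in neither setting counted as kept. For example, the neural level went from percentile 88.5 to 17.5 at a mean count of at least 10. The 351 detected loci became 563 with a minimum of 1 count, and the share of the 10 most abundant loci, 43.0%, became 41.6% with counts irrespective of strand, which adds opposite-strand counts to the total. Pearson's r of 0.990 was 0.992 at a mean count of at least 10, and 0.984 and 0.996 with pseudocounts of 0.5 and 5. The 5 loci past 2-fold were 13 at a mean count of at least 20 and 3 at 500; TMM, DESeq2 factors, thinning, strand and leaving out Mir335 each gave 5. The numbered-copy difference of -15.5 points was reversed to 43.4 points with shared hairpins, which classes 929 rather than 121 loci. Of the list percentiles, the let-7 level became high without numbered copies (99.1), the Mir322 and Mir503 level lost its call at a mean count of at least 10 (87.0), and at a mean count of at least 50 the neural difference between pools gained a call (1.63) and that of let-7 lost one (2.74), as it did with opposite-strand counts credited to the gene there (2.77), where 6 rather than 7 lists were called; the causes were not tested. All 292 recomputed ratios of single loci between pools kept their side of 2-fold. For TMM and DESeq2 factors this says little, since they changed the log2 ratio of library sizes by only -0.0018 and -0.0032. Leaving out either replicate kept every list level on its side of the limits. Depth limits loci with few counts: Mir486, with 31 and 49 counts, had an interval of -0.27 to 1.10. No paired analysis was possible because there is only 1 group.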

Other observations

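The families and all tests of this part were chosen after the values were seen, except the tests on Mir490 and on further loci of the Htr2c cluster.

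Other abundant families, picked after their values were seen, stood beside the fixed lists. The miR-99 and miR-100 loci took 9.72% ± 0.49 (SD, n = 2) of the counts from 3 loci, more than the let-7 list. The let-7 total is incomplete: of 14 listed loci 10 were measured. Of these, 5 are numbered copies, which can lose reads to the class placed at several positions. The miR-130 and miR-301 loci took 4.85% ± 0.29, mainly through Mir130a at 36133 CPM and Mir130b at 9568 CPM. The miR-30 loci took 3.60% ± 0.14, led by Mir30e, with Mir30a at 6397 CPM and Mir30d at 3456 CPM. The miR-181 loci took 2.17% ± 0.10, led by Mir181d and Mir181c at 8452 and 7791 CPM. The miR-181a, miR-181b and miR-30c loci are numbered copies that can lose reads in the same way. The shares of these families and the order within them are therefore uncertain.

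Some loci known from heart muscle, blood and liver (Mir208a, Mir208b, Mir499, Mir451a, Mir122) were higher in replicate 2 and some expressed in the eye (Mir184, Mir204, Mir211) in replicate 1, groupings made after the values were seen: Mir192 (0.04), Mir194-2 (-0.21), Mir144 (-0.02) and Mir182 (0.27) did not follow them, and of the lists concerned the erythroid (91.6) and liver (44.7) ones passed no limit. More erythroid cells in replicate 2 stay open: with the spread between pools included, the log2 ratio of Mir451a exceeded that of Mir144 by 1.35 (0.30 to 2.40) and that of Mir486 by 0.93 (-0.24 to 2.09), an interval that includes 0. More heart tissue in replicate 2 may account for the myosin-hosted loci, but the prediction for Mir490 written beforehand failed: its log2 ratio was -1.06 (-2.52 to 0.29), and its upper bound lay below the lower bound of Mir208b (1.68), which by that prediction counts against heart tissue. It is left open for a reason found only afterwards: Mir490 had 14 and 8 counts, and tissue with replicate 2's ratio of Mir490 to Mir208b would bring only 1.87 of the 14. More eye or choroid tissue in replicate 1 also stays open, since 3 further Htr2c loci gave a pooled log2 ratio of -0.81 (-1.51 to -0.13; 47 and 32 counts) while their median, that of Mir448, was -0.33 and did not pass the bound predicted for it; the design names no biological difference between the pools, so none was tested.

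A hypothesis that clustered loci differ alike between the pools, through shared transcription, was tested on 92 adjacent pairs of loci on 1 strand. Their log2 ratios between pools differed by 0.176 on average, against 0.210 when ratios were permuted over the 129 loci of these pairs (two-sided permutation test, p = 0.0099). Permuting over all 257 loci, which mixes in unclustered loci with larger differences, gave 0.322. The smaller gap is consistent with a modest share of the difference between pools being common to neighbours. Among the pairs that differ most are Mir542 and Mir351 (-0.04 and 0.81) and Mir351 and Mir503 (0.81 and 0.16).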
